A study of Mus musculus with 9 samples.

How the data were processed

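RNA from kidneys of wild-type mice was sequenced in 9 libraries, 3 from each of 3 groups: surgery without ischemia-reperfusion injury (sham), injury with phosphate-buffered saline (AKI_PBS), and injury with milk-derived extracellular vesicles carrying an siRNA against PTP1B (AKI_PTPi_mEVs). Per the labels' protocols, RNA was extracted with phenol-chloroform, and libraries were made from 100 ng of total RNA with a Tn5-based kit. The values are whole-number counts per gene, as deposited, and STAR and HTSeq were used to make them, per the submitters' processing notes, which give no versions. The same notes name the build GRCh38.p14, which is human, while all 56923 gene identifiers are mouse Ensembl identifiers, so the build was not settled and no coordinates are given. Filters and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes could not be told apart. One title of a treated library spells the vesicles differently from its treatment label, and the group was taken from the treatment label.

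Columns were matched to samples by the names in the labels, and 0 columns of per-sample values were left unmapped. Symbols were found for 52073 identifiers and not for 4850. Library totals lay between 9467851 and 11389479 counts (ratio 1.20). Counting intervals cover counting error only and leave out the spread between libraries. Reads carried no molecular identifiers, so copies from amplification could not be told apart from separate molecules, and these intervals may be too narrow. Within groups no libraries were duplicates.

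Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group left 17036 genes, TMM factors scaled the libraries, and glmQLFit (robust) with a mean per group was fitted to all 9 libraries together, with 6 residual degrees of freedom. The 3 pairs of groups were compared with glmQLFTest, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Ptpn1 was also compared by two-sided exact permutation tests. The 41 gene lists were fixed before the data were examined. They hold 735 names, of which 729 were matched, each to a different member of its list. Bmal1, Atp5a1 and Atp5b named genes also written under a newer or older name, Rigi is a name of the listed Ddx58, and Ahsp and Ptprg were not found. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and beside it with an estimated correlation and with fry.

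The rule for named genes was also fixed before the data were examined: a panel of 18 genes, the 6 largest rises and the 6 largest falls among called genes with a mean log2 CPM of at least 2 and groups that do not overlap (gene models named Gm or ending in Rik left out), and up to 4 members with the smallest adjusted p from each list, or up to 2 where none passed. Genes named outside the rule (Cirbp, Rbm3, Malat1, Neat1, Mcm4, Mcm7, the clock genes beyond 4 and the chaperones beyond 4) were chosen after their values were seen. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with a 95% exact interval. Fibrinogen, serum amyloid, metallothionein and haemoglobin genes have close copies between which the counting could split reads.

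The fit was tested on simulated counts with 200 changed genes. Over 5 runs it recovered 59.4% of 2-fold and 93.3% of 4-fold changes for AKI_PBS against sham, 59.8% and 94.4% for AKI_PTPi_mEVs against AKI_PBS, and 58.4% and 93.2% for AKI_PTPi_mEVs against sham. Of the calls, 6.88%, 6.79% and 6.75% were false in these comparisons, more than the threshold of 0.05 aims at. The real comparisons called 9488, 8711 and 2252 genes, many more than were changed in the simulation. These shares therefore describe the simulated setting and need not hold for the data. The number of runs was raised to 5 after a single run had been seen. In AKI_PBS against sham, the comparison in which lists were simulated, a shift of the unfolded protein response list by 0.5 on the log2 scale was recovered with 0 other lists called.

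For the return toward sham, 20 simulated groups at the AKI_PBS level gave the values that shared libraries produce without an effect. The 3 AKI_PBS libraries could not be split into parts of at least 2. Alternatives fixed before the data were examined were relative log expression size factors, library totals, DESeq2 1.42.0, limma voom, no low-count filter and a stricter one, only the groups compared, a replicate block, each library left out, and a log2 fold change of at least 1. A correction for GC content and transcript length and thinning to the lowest total were added after seeing the data. Python 3.11.15 and matplotlib 3.10.9 drew the figures.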

Results

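Gene expression was measured by RNA sequencing in kidneys of wild-type mice from 3 groups with 3 libraries each. The sham group had surgery without ischemia-reperfusion (IR) injury. The AKI_PBS group had acute kidney injury (AKI) and received phosphate-buffered saline, and the AKI_PTPi_mEVs group had the same kind of injury and received milk-derived extracellular vesicles loaded with an siRNA against PTP1B, the tyrosine phosphatase encoded by Ptpn1. The series asks what PTP1B does in acute kidney injury. Library totals lay between 9467851 and 11389479 counts, and 17036 genes were tested. The libraries hold no group labelled as injured and given empty vesicles or a control siRNA, so a difference between the injured groups is one between PBS and the loaded vesicles as a whole. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these samples. The labels also give neither the time after injury nor a library batch, so a difference in either cannot be told apart from the group. Values after ± are standard errors of the log2 fold change unless SD is written, n = 3 per group throughout, and gene-level calls are from edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05.

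The targeted gene, Ptpn1 (ENSMUSG00000027540.14), was examined first. Its level, in counts scaled by library total and TMM factor (CPM), was 90.1 ± 8.91 CPM (SD) in sham, 147 ± 23.8 CPM (SD) in AKI_PBS and 102 ± 6.94 CPM (SD) in AKI_PTPi_mEVs. The sham libraries held 80.9, 90.5 and 98.8 CPM, the AKI_PBS libraries 123, 148 and 170 CPM, and the AKI_PTPi_mEVs libraries 106, 106 and 94.0 CPM. Ptpn1 rose in AKI_PBS against sham (log2 fold change 0.71 ± 0.15, edgeR adjusted p = 0.0012) and was lower in AKI_PTPi_mEVs than in AKI_PBS by 30.7% (log2 fold change -0.53 ± 0.15, edgeR adjusted p = 0.0086). Against sham, AKI_PTPi_mEVs differed by 0.18 ± 0.15, which did not pass (edgeR adjusted p = 0.46). Two-sided exact permutation tests of the CPM values gave p = 0.1, 0.1 and 0.2 for these 3 comparisons, where 0.1 is the smallest p that 3 against 3 libraries allow.

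**Figure D1:**
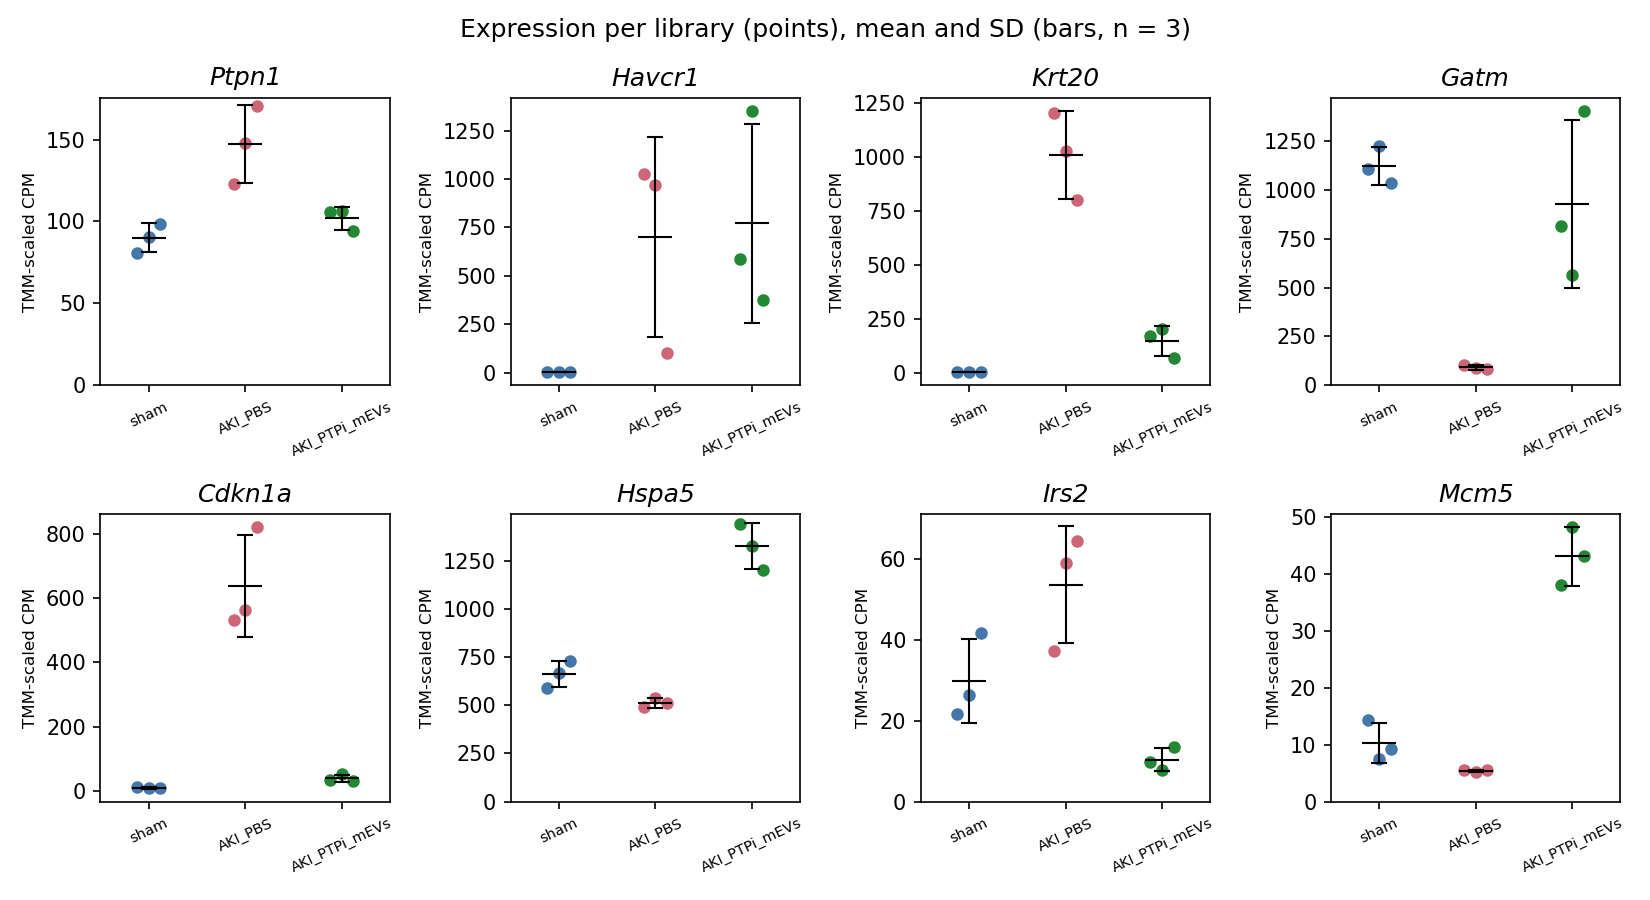
TMM-scaled CPM (vertical axes, linear) of 8 genes in each library, by group; points are libraries and bars the mean and SD of 3 libraries. The AKI_PBS libraries held 123 to 170 CPM of Ptpn1 and the AKI_PTPi_mEVs libraries 94.0 to 106 CPM, while Havcr1 overlapped between the injured groups.

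Injury with PBS was compared with sham to describe the injured kidney. Genes of tubular injury rose together: 26 of 27 measured members passed (26 adjusted over the list alone), with a median log2 fold change of 2.74. Among them Krt20, a keratin of injured epithelium, rose by 8.77 ± 0.46, Lcn2, which encodes the injury marker NGAL, by 7.60 ± 0.42, and Cdkn1a, the cell cycle inhibitor p21, by 5.86 ± 0.27. Proximal tubule genes fell, 29 of 33 (29 adjusted over the list alone; median -1.42), including Gatm, a creatine synthesis enzyme (-3.61 ± 0.28), the water channel Aqp1 (-2.77 ± 0.24) and the phosphate transporter Slc34a1 (-1.33 ± 0.23). In all, 9488 of 17036 genes changed, 4734 higher and 4754 lower, of which 2383 and 2844 changed at least 2-fold. With library totals in place of TMM factors 5250 were higher and 4301 lower. The first principal component held 64.7% of the variance and set the AKI_PBS libraries apart from both other groups. AKI_PBS replicate 3 stood apart within its group: on the third component, which held 6.27% of the variance, it lay at -44.1 and the other AKI_PBS libraries at 28.3 and 20.6.

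Further nephron segments lost transcripts in AKI_PBS. Of 12 loop of Henle genes, 10 fell (10 adjusted over the list alone; median -1.93), with Cldn10 at -3.41 ± 0.18 and Kcnj1 at -2.40 ± 0.15. Of 10 collecting duct principal cell genes, 7 fell (7 adjusted over the list alone), with Elf5 at -3.15 ± 0.33. Both lists passed camera with its preset correlation (adjusted p = 9.87e-05 and 0.0126), as did tubular injury (adjusted p = 2.25e-11) and proximal tubule (adjusted p = 1.41e-09). With an estimated correlation none of these calls held: adjusted p = 0.243 for tubular injury, loop of Henle and collecting duct principal cell, and adjusted p = 0.466 for proximal tubule. The distal convoluted tubule list had 2 members higher and 6 lower of 10 and the intercalated cell list 4 lower of 11, and neither passed camera (adjusted p = 0.283 and 0.281).

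Of the inflammatory and stress lists 7 were called higher in AKI_PBS by camera at the preset correlation (adjusted p = 1.05e-07 to 0.0074), and none with an estimated one. The latter gave adjusted p = 0.243 for neutrophil, immediate early, NRF2 and p53, adjusted p = 0.322 for cytokine and glucocorticoid, and adjusted p = 0.623 for NF-kB. The lists of complement, unfolded protein response, heat shock, nucleic acid sensor and necroptosis were not called, and interferon response genes fell in 12 of 21. All 9 measured of 17 listed neutrophil genes rose (9 adjusted over the list alone, median 6.19, or 5.35 with genes absent from sham at their lower bound). S100a8, Retnlg and Mmp8 had 113, 137 and 137 counts in AKI_PBS, 5, 4 and 2 in AKI_PTPi_mEVs and 0 in sham. Ngp, S100a9 and Cxcr2 had 105, 131 and 80 counts in AKI_PBS, 0, 5 and 6 in AKI_PTPi_mEVs and 3, 2 and 1 in sham. Those of these genes that were measured could pass the low-count filter only through AKI_PBS, so for them the direction was fixed in advance. The number of neutrophil genes that rose and their median rest partly on them. S100a8, an alarmin of neutrophils, had 0 counts in sham and was at least 33.6-fold higher against a floor of 3 counts over the group. Immediate early genes rose in 16 of 17 (16 adjusted over the list alone; median 3.20), with Klf6 at 3.32 ± 0.25 and Atf3 at 5.36 ± 0.48. Cytokine and chemokine genes rose in 11 of 16 (11 adjusted over the list alone; median 2.19) and NF-kB targets in 13 of 18 with 2 lower (13 and 2 adjusted over the list alone), among them Cxcl2 (6.41 ± 0.63) and Nfkbiz (3.28 ± 0.37). Ccl2 rose by 1.57 ± 0.37 and Cxcl1 by 4.40 ± 0.96, a value that fell to 2.67 without AKI_PBS replicate 3. NRF2 and ferroptosis genes rose in 15 of 26 with 1 lower (15 and 1 adjusted over the list alone), led by the metallothionein Mt2 (4.60 ± 0.28) and by Hmox1, heme oxygenase 1 (2.85 ± 0.23). Glucocorticoid response genes rose in 10 of 12 (10 adjusted over the list alone, median 1.93), with Fkbp5 at 2.10 ± 0.20. The p53 and apoptosis genes rose in 17 of 27 with 2 lower (17 and 2 adjusted over the list alone), with Mcl1 at 1.86 ± 0.15. Per1, Dusp1, Mt1, Mt2 and Cdkn1a of the glucocorticoid list also belong to other lists described here, so these lists are not separate evidence.

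Genes of PTP1B substrates and of insulin or leptin signalling rose in 14 of 28 and fell in 3 (14 and 3 adjusted over the list alone), and the list was called higher (camera adjusted p = 0.0098; adjusted p = 0.623 with an estimated correlation). Its leading members were Socs3, a feedback inhibitor of cytokine signalling (5.10 ± 0.27), and Stat3 (2.48 ± 0.17). Insr, the insulin receptor, did not pass (0.37 ± 0.16), but did without AKI_PBS replicate 1 (0.46) or 2 (0.46) and with library totals (0.44). Irs2, an adaptor of the insulin receptor, rose by 0.84 ± 0.26, a call lost without sham replicate 1, sham replicate 2, AKI_PBS replicate 2 or AKI_PBS replicate 3. Protein tyrosine phosphatase genes, Ptpn1 included, went both ways, with 12 of 25 higher and 4 lower (12 and 4 adjusted over the list alone). The list did not pass camera (adjusted p = 0.147) but passed fry (adjusted p = 0.0014). Ptpn12 rose by 2.08 ± 0.22 and Ptpn6 fell by 1.41 ± 0.18 on the log2 scale. Of the interferon response genes 12 of 21 fell and 2 rose (12 and 2 adjusted over the list alone), with Ifit3 at -2.19 ± 0.23. Nuclear oxidative phosphorylation genes fell in 13 of 27 (13 adjusted over the list alone), and ribosomal protein genes rose in 16 of 26 (16 adjusted over the list alone). These 3 lists passed camera at the preset correlation (adjusted p = 0.0097, 0.0144 and 0.0042), and with an estimated correlation adjusted p = 0.711, 0.730 and 0.809. The order is interferon, oxidative phosphorylation and ribosomal protein, and the last call was also lost with fry (adjusted p = 0.067). In all 15 lists were called in this comparison. The other splits of its 6 libraries called 5 to 18, but each of them mixes libraries of both groups on both sides. Part of the group difference stays in such splits, so they are no reference without an effect.

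The genes with the largest rises at moderate expression were Il1f6, Sprr2f, Fgb, Krt20, Fosl1 and Havcr1, and those with the largest falls Cldn11, Prss35, A4gnt, Ccl28, BC024386 and Hsd3b2. Havcr1, which encodes the injury marker KIM-1, rose by 8.30 ± 1.11, and Cldn11, a tight junction gene, fell by 6.78 ± 0.43 on the log2 scale. Il1f6 was at 0 counts in sham and at least 75.8-fold higher, so its rank among the rises rests on a fitted fold and is not settled. Sprr2f and Fosl1 had 3 counts and 1 count in sham, so their ranks are not settled either. Their pooled ratios were 568 (95% exact interval for counting error 194 to 2758) and 550 (98.4 to 21763). Il6 did not pass the low-count filter, which asks for a minimum count in each of several libraries. It had 1 count in sham and 107 in AKI_PBS over 3 libraries each. The pooled ratio was 95.4 (95% exact interval for counting error 16.8 to 3803), which leaves out the spread between libraries. Adgre1, which encodes the macrophage marker F4/80, fell by 2.44 ± 0.52 at a level of 1.77 CPM in sham. Malat1 and Neat1, nuclear non-coding RNAs, together took 0.864 ± 0.157% (SD) of counts in AKI_PBS and 0.336 ± 0.0240% (SD) in sham, beside the gene groups above. Urothelium genes were lower in 5 of 8 and higher in 1 (6 and 1 adjusted over the list alone) and did not pass as a list (camera adjusted p = 0.0816), with Upk3b at -3.39 ± 0.48. Red blood cell genes did not pass as a list (camera adjusted p = 0.856), and platelet genes, 2 of 3 higher, did not pass either (camera adjusted p = 0.452).

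AKI_PTPi_mEVs was compared with AKI_PBS to describe injured kidneys given the loaded vesicles. Proximal tubule genes were higher, 22 of 33 with 1 lower (23 and 1 adjusted over the list alone, median 1.14), including Gatm (3.33 ± 0.28) and Aqp1 (2.61 ± 0.24). Loop of Henle genes were higher in 7 of 12 with 1 lower, and collecting duct principal cell genes in 6 of 10 with 1 lower. Neither passed camera (adjusted p = 0.0508 for both), while fry passed both (adjusted p = 0.0016 and 0.00056). Distal convoluted tubule genes were higher in 2 of 10 and lower in 3 (camera adjusted p = 0.465). All 17 immediate early genes were lower (17 adjusted over the list alone; median -2.27), with Fosl1 at -3.73 ± 0.35. Tubular injury genes were lower in 17 of 27 and higher in 1 (17 and 1 adjusted over the list alone; median -1.06): Krt20 fell by 2.78 ± 0.33, Lcn2 by 2.24 ± 0.30 and Cdkn1a by 3.97 ± 0.24 on the log2 scale. Havcr1 did not pass (0.14 ± 0.76, edgeR adjusted p = 0.89), and its standard error is too large to tell whether it shared this change. AKI_PBS replicate 3 held 104 CPM of Havcr1 against 1025 and 971 CPM in the other AKI_PBS libraries. The AKI_PTPi_mEVs libraries held 585, 1350 and 375 CPM. The log2 fold change of Havcr1 was -0.37 without AKI_PBS replicate 3 and -0.53 without AKI_PTPi_mEVs replicate 2. After a correction for GC content and transcript length it was -0.10, and none of these passed. Over all genes 8711 changed, 4320 higher and 4391 lower, of which 2282 and 2288 changed at least 2-fold. The balance depended on the scaling, since with library totals 3757 were higher and 5048 lower.

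Other groups also differed between the injured groups. Neutrophil genes were lower in 8 of 9 (9 adjusted over the list alone, median -4.37), with Il1r2 at -5.91 ± 0.48. S100a8, Retnlg and Mmp8, and Ngp, S100a9 and Cxcr2 where measured, could pass the filter only through AKI_PBS. For them this direction was fixed in advance, so the neutrophil count and median rest partly on them. Genes of other blood cells were lower beside them: red blood cell genes in 5 of 7 with 1 higher (5 and 2 adjusted over the list alone; median -2.21) and platelet genes in 2 of 3 (2 adjusted over the list alone; median -2.58), though neither passed as a list (camera adjusted p = 0.22 and 0.317). Glucocorticoid response genes were lower in 11 of 12 (11 adjusted over the list alone, median -2.40). Among them were Per1 at -2.75 ± 0.20 and Mt1 at -2.87 ± 0.21, which are also in the clock and NRF2 lists. Fatty acid oxidation and peroxisome genes were higher in 15 of 25 and lower in 2 (15 and 2 adjusted over the list alone), with Cyp4a10, a fatty acid hydroxylase, at 1.85 ± 0.25. Urothelium genes were higher in 6 of 8 (6 adjusted over the list alone), with Upk3b, a bladder and urothelial surface protein gene, at 3.64 ± 0.48. Mitochondrially encoded genes were lower in 10 of 14 (11 adjusted over the list alone), with mt-Nd5 at -0.93 ± 0.15, and took 1.32 ± 0.0835% (SD) of counts in AKI_PTPi_mEVs and 2.23 ± 0.199% (SD) in AKI_PBS. Beside them Malat1 was at -1.12 ± 0.15 and Neat1 at -1.55 ± 0.23, and their share was 0.327 ± 0.00822% (SD) in AKI_PTPi_mEVs. Ribosomal protein genes were lower in 7 of 26 (6 adjusted over the list alone). Of the PTP1B substrate and insulin or leptin list, 13 of 28 were lower and 1 higher (13 and 1 adjusted over the list alone), with Irs2 at -2.37 ± 0.28, Stat3 at -1.29 ± 0.16 and Socs3 at -1.87 ± 0.22. Protein tyrosine phosphatase genes were lower in 10 of 25 and higher in 7 (10 and 7 adjusted over the list alone). That list did not pass camera (adjusted p = 0.167) but passed fry (adjusted p = 0.0056). Insr did not pass (-0.37 ± 0.16), but did without AKI_PBS replicate 1 (-0.46) or 2 (-0.47) and with library totals (-0.47).

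In this comparison 10 lists were called by camera at the preset correlation, 3 higher and 7 lower (adjusted p = 1.25e-06 to 0.032). The number was 16 without AKI_PBS replicate 3, and the other splits of the 6 libraries, which mix the groups, called 6 to 18. None was called with an estimated correlation. It gave adjusted p = 0.410 for neutrophil and adjusted p = 0.553 for immediate early and glucocorticoid response. It gave adjusted p = 0.719 for tubular injury, proximal tubule, mitochondrially encoded and PTP1B substrate, and adjusted p = 0.748 for ribosomal protein, fatty acid oxidation and urothelium. The last 3 of these calls were also lost without AKI_PBS replicate 2, those of urothelium and ribosomal protein without AKI_PTPi_mEVs replicate 1, and that of ribosomal protein without AKI_PBS replicate 1 and with fry. Hspa5, the endoplasmic reticulum chaperone BiP, was higher by 1.37 ± 0.14, while Ddit3, the stress factor CHOP, did not pass (0.04 ± 0.17). The unfolded protein response list had 14 of 27 higher and 4 lower (14 and 5 adjusted over the list alone) and did not pass (camera adjusted p = 0.0907). Cytokine and chemokine genes were lower in 6 of 16 and higher in 2 and did not pass as a list (camera adjusted p = 0.305); Cxcl1 did not pass (-1.74 ± 0.82) except without AKI_PBS replicate 1 (-2.21). Ccl2 was at -0.99 ± 0.35 and passed, a call lost with DESeq2, with no low-count filter, with thinned libraries, without AKI_PBS replicate 2 or 3 and without any one of the AKI_PTPi_mEVs replicates. Haemoglobin genes, which have near-identical copies between which the counting could split reads, were lower, with Hba-a1 at -2.39 ± 0.30. The largest rises were those of Cldn11, Prss35, Gsdmc3, Insc, Gcnt3 and Gsdmc2, and the largest falls those of Sult1e1, Il1r2, Pdk4, Adh6a, Slc10a6 and Pi15. Sult1e1 had 628 counts in AKI_PBS, 8 in AKI_PTPi_mEVs and 2 in sham. It could pass the low-count filter only through AKI_PBS, so its direction was fixed in advance. Cldn11 was higher by 7.63 ± 0.42 and Pdk4, a kinase that restrains pyruvate oxidation, was lower by 5.77 ± 0.50.

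The changes were set against each other gene by gene to measure how far expression in AKI_PTPi_mEVs lay back toward sham. Whether both injured groups were collected at the same time after injury is not given in the labels. Of the 9488 genes changed by injury, 9010 had the opposite sign in AKI_PTPi_mEVs against AKI_PBS, 6905 (72.8%) passed the threshold in that direction and 39 passed it further from sham. Of those changed by injury, 1509 still differed from sham on the same side. That number was 889 without sham replicate 1, 712 without sham replicate 2, 666 without AKI_PTPi_mEVs replicate 2 and 2116 without AKI_PBS replicate 3. On the other side of sham were 162. This second count was 57, 40 and 93 without sham replicates 1, 2 and 3, 263 without AKI_PBS replicate 3, and 100, 56 and 87 without AKI_PTPi_mEVs replicates 1, 2 and 3. Placed on the axis from sham (0) to AKI_PBS (1), the AKI_PTPi_mEVs libraries lay at 0.257 ± 0.0684 (SD). That axis leaves out other differences. On the second principal component (15.0% of the variance) the AKI_PTPi_mEVs libraries lay at -33.9, -53.1 and -33.7. The sham libraries lay there at 35.8, 31.7 and 31.7, and AKI_PBS between them at -6.35, 4.36 and 23.3. A further 431 genes were not called in AKI_PBS against sham, but AKI_PTPi_mEVs differed from both groups in them. The comparisons share the AKI_PBS libraries, which by itself turns signs: with AKI_PTPi_mEVs simulated at the AKI_PBS level, 55.7% of changed genes had the opposite sign over 20 runs (54.6 to 56.7%), and 0 to 1 genes passed the threshold in that direction. The covariance of the fold changes across genes, which are not independent replicates, was -1.26 and the simulated one -0.047. Genes higher after injury and lower with the vesicles numbered 3475, where independent lists would share 1220, and those with the reverse pattern 3430, where independent lists would share 1206; part of the excess may come from the shared libraries.

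**Figure D2:**
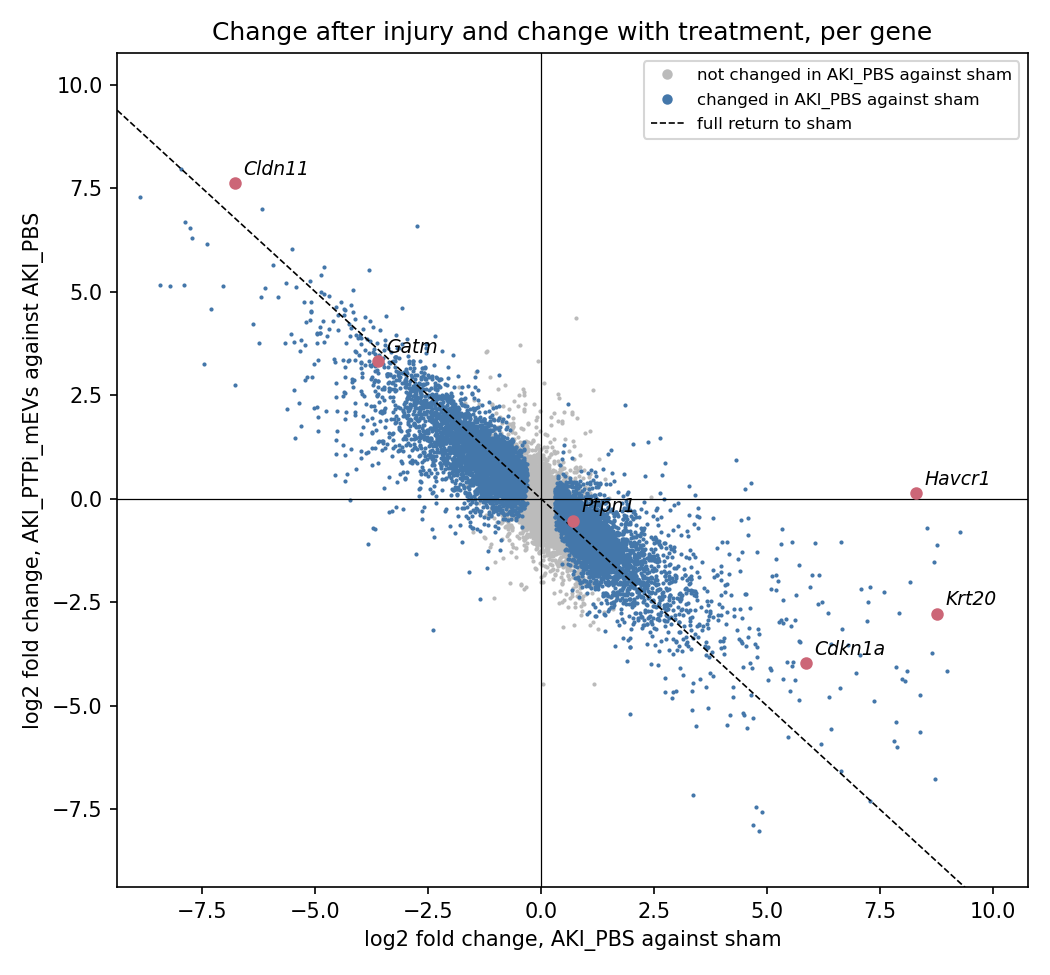
Log2 fold change in AKI_PBS against sham (horizontal axis) and in AKI_PTPi_mEVs against AKI_PBS (vertical axis) for each of 17036 genes; blue points passed the threshold in AKI_PBS against sham, grey points did not, red points are named genes and the dashed line marks full return to sham. Of the 9488 blue points 9010 have opposite signs on the axes, and Havcr1 lies near 0 on the vertical axis.

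AKI_PTPi_mEVs was compared with sham to describe what still differed. Tubular injury genes were higher, 24 of 27 (24 adjusted over the list alone; median 1.62), including Krt20 (5.99 ± 0.42), Lcn2 (5.36 ± 0.40) and Havcr1 (8.44 ± 1.11). Genes of the unfolded protein response were higher in 13 of 27 (15 adjusted over the list alone), with Pdia4, a protein disulfide isomerase, at 1.02 ± 0.15. Hspa5 was among them, at 1326 ± 119 CPM (SD) in AKI_PTPi_mEVs and 663 ± 68.0 CPM (SD) in sham (edgeR adjusted p = 0.00087). The 4 genes that passed in the proliferation list belong to the MCM complex, the helicase that licenses DNA replication, with Mcm5 at 2.06 ± 0.22 and Mcm3 at 2.36 ± 0.26, although the list as a whole, 4 of 22 higher (5 adjusted over the list alone), did not pass (camera adjusted p = 0.0675). Irs2 was below sham (-1.53 ± 0.28). Its PTP1B substrate and insulin or leptin list had 3 of 28 higher and 1 lower (3 and 1 adjusted over the list alone) and did not pass (camera adjusted p = 0.354). In all 2252 genes changed, 1266 higher and 986 lower. That count moved when a library was left out. It was 1184, 938 and 1599 without sham replicates 1, 2 and 3, and 1487, 878 and 1771 without AKI_PTPi_mEVs replicates 1, 2 and 3. Fewer libraries also give less power, so these lower counts do not single out a library. Without AKI_PBS replicate 3, a library in neither of the groups compared, the count was 3395, and with only the 2 groups compared it was 3259. The main fit shares 1 estimate of spread over all 9 libraries, so the spread within AKI_PBS enters the count of 2252.

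Of the other lists higher than sham, NRF2 and ferroptosis had 12 of 26 (15 adjusted over the list alone; Hmox1 1.70 ± 0.23), cytokine and chemokine 9 of 16 with 1 lower (10 and 1 adjusted over the list alone; Csf1 1.79 ± 0.31), p53 and apoptosis 8 of 27 (10 adjusted over the list alone; Pmaip1 1.67 ± 0.26) and NF-kB targets 7 of 18 with 1 lower (7 and 1 adjusted over the list alone; Bcl3 1.25 ± 0.21). Immediate early genes had 6 of 17 higher and 1 lower (6 and 1 adjusted over the list alone; Atf3 2.91 ± 0.50), and liver and acute phase genes 5 of 12 higher and 1 lower (5 and 2 adjusted over the list alone), with the fibrinogen gene Fgg at 5.58 ± 0.58. Neutrophil genes were called with 1 of 9 higher (2 adjusted over the list alone; adjusted p = 0.273 with an estimated correlation), which was Lcn2, a gene that injured tubules also express. The milk protein list was called (adjusted p = 0.429 with an estimated correlation) on Xdh (1.12 ± 0.18) and Muc1 (0.75 ± 0.17), which the kidney expresses itself. Xdh was also higher than sham in AKI_PBS, which had no vesicles (2.49 ± 0.19), where the list had 2 of 3 higher and did not pass (camera adjusted p = 0.124). The call of Muc1 was lost without sham replicate 3, AKI_PTPi_mEVs replicate 1 or AKI_PTPi_mEVs replicate 2. Glycolysis and hypoxia had 1 of 22 higher and 1 lower (9 and 2 adjusted over the list alone). Lists lower than sham were mitochondrially encoded, 5 of 14 (13 adjusted over the list alone), distal convoluted tubule, 5 of 10 (7 adjusted over the list alone; Pvalb -2.42 ± 0.32), loop of Henle, 7 of 12 with 1 higher (8 and 1 adjusted over the list alone; Ppp1r1a -1.17 ± 0.15), proximal tubule, 8 of 33 with 1 higher (9 and 1 adjusted over the list alone; Ttc36 -1.96 ± 0.23), and nuclear oxidative phosphorylation, 8 of 27 (10 adjusted over the list alone).

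Red blood cell genes were lower in 5 of 7 (6 lower and 1 higher adjusted over the list alone; Hba-a1 -1.75 ± 0.30), beside the lower mitochondrial genes, and intercalated cell genes in 2 of 11 (4 adjusted over the list alone), interferon response genes in 3 of 21 with 1 higher (9 and 2 adjusted over the list alone) and adipose tissue genes in 2 of 8 (2 adjusted over the list alone). The endothelial cell list was called lower with 0 of 16 members past the edgeR threshold and 7 at an unadjusted p under 0.05 (adjusted p = 0.680 with an estimated correlation); Ptprb was at -0.66 ± 0.21. These 21 calls, 11 higher and 10 lower, used camera's preset correlation (adjusted p = 7.08e-19 to 0.0485). The other splits of the 6 libraries, which mix the groups, gave 9 to 14 calls. None of the 21 held with an estimated one: adjusted p = 0.238 for tubular injury, unfolded protein response, NRF2, cytokine, p53 and loop of Henle, adjusted p = 0.415 for distal convoluted tubule, adjusted p = 0.429 for glycolysis and mitochondrially encoded, and adjusted p = 0.273 to 0.726 for the other 12. The interferon response call was also lost with library totals, with fry and without any one library other than sham replicate 3 and AKI_PTPi_mEVs replicate 1, and that of adipose tissue with library totals, with fry and without sham replicate 2, sham replicate 3 or AKI_PTPi_mEVs replicate 3. Glycolysis and hypoxia lost its call without sham replicate 1, sham replicate 2 or AKI_PTPi_mEVs replicate 1, and the endothelial list without AKI_PTPi_mEVs replicate 3. With fry, which does not compare a list with other genes, the calls of endothelial cell, proximal tubule, intercalated cell, red blood cell, liver, NF-kB, oxidative phosphorylation and immediate early were lost as well. The largest fitted rises were those of Il1f6, Havcr1, Fgb, Krt20, Fgg and Lcn2, and the largest falls those of Upp2, Kcnt1, Rnf24, ENSMUSG00000121494, Itih2 and Vmn1r18. Il1f6 had 0 counts in sham, so its rank is not settled. Fgb at 7.66 ± 1.31 lost its call without sham replicate 2 or 3 and with limma voom, and Il1f6, at least 41.6-fold higher, lost its call without AKI_PTPi_mEVs replicate 2.

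**Figure D3:**
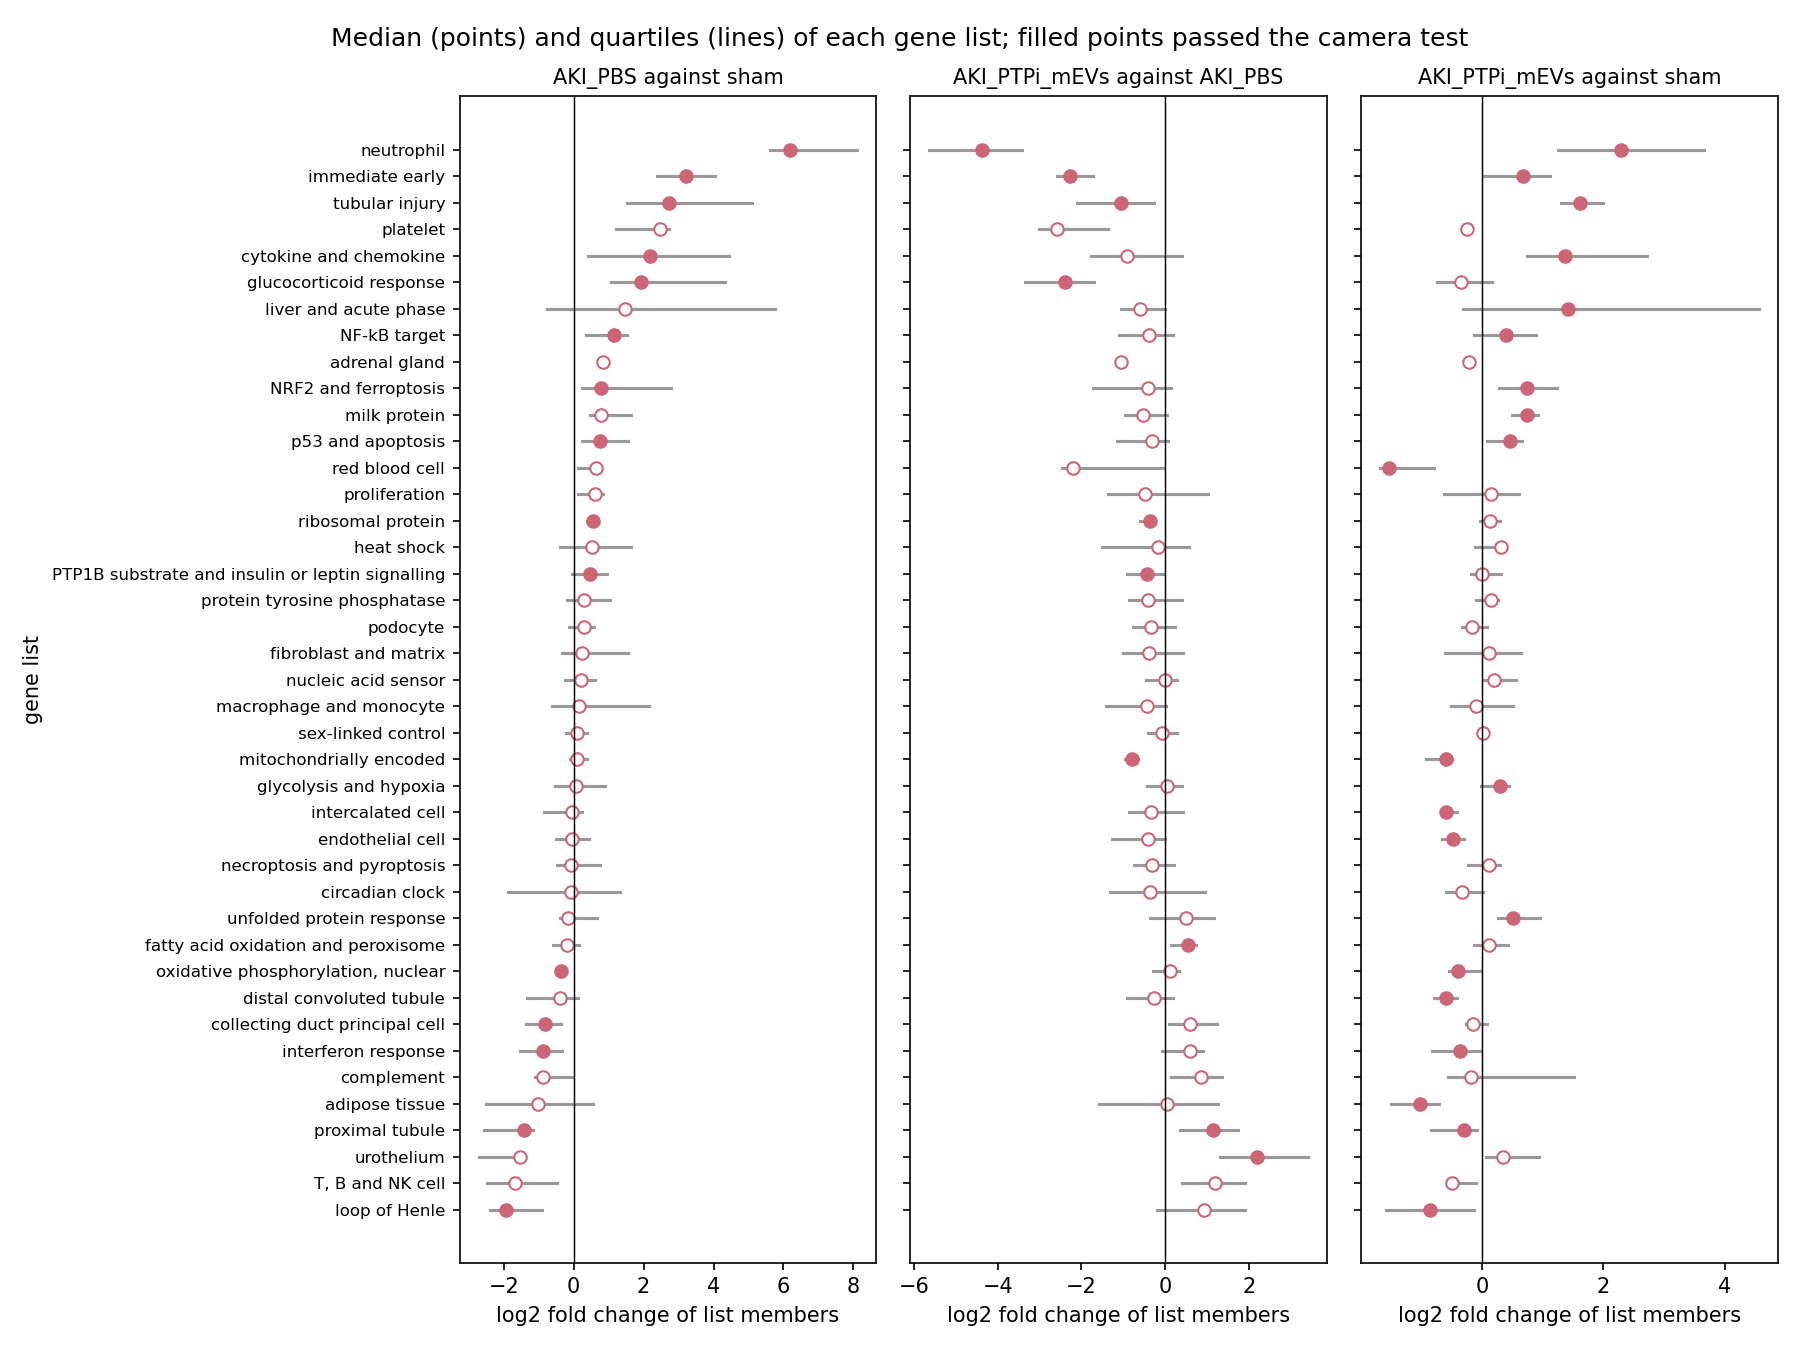
Median log2 fold change (points, horizontal axes) and quartiles (lines) of the members of 41 gene lists (vertical axis) in the 3 comparisons; filled points passed camera with its preset correlation at an adjusted p under 0.05, and none passed with an estimated correlation. The tubular injury median was 2.74 in AKI_PBS and 1.62 in AKI_PTPi_mEVs, both against sham.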

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

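The GC and length correction and the thinning were chosen after the results were seen; all other alternatives were fixed before the data were examined. The counts of changed genes in AKI_PBS against sham and in AKI_PTPi_mEVs against AKI_PBS stayed within 1.5 times under each alternative other than a log2 fold change of at least 1, which left 5227 and 4570 genes by its own construction. With 1 library left out they ranged from 8028 to 9650 and from 7337 to 8743. For AKI_PTPi_mEVs against sham the count was 987 with the fold threshold and ranged from 878 to 3395 with 1 library left out: 1184 without sham replicate 1, 938 without sham replicate 2, 3395 without AKI_PBS replicate 3, and 1487 and 878 without AKI_PTPi_mEVs replicates 1 and 2. Genes that moved back past the threshold numbered 5930 to 6963 with 1 library left out and 4154 with the fold threshold. Genes changed by injury that still differed from sham numbered 666 to 2116 on the same side and 40 to 263 on the other with 1 library left out, the latter 260 with no low-count filter and 62 with the fold threshold. The share with the opposite sign was 93.7 to 96.3%. Ptpn1 ranged from 0.59 to 0.82 in AKI_PBS against sham, from -0.63 to -0.40 in AKI_PTPi_mEVs against AKI_PBS (highest edgeR adjusted p = 0.0469) and from 0.11 to 0.26 in AKI_PTPi_mEVs against sham. Library totals moved the median of all genes by -0.106 in AKI_PTPi_mEVs against AKI_PBS. After the GC and length correction 9489, 8631 and 2229 genes were called in the 3 comparisons, and after thinning 9245, 8568 and 2210.

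Gene lists called numbered 15 to 16 in AKI_PBS against sham, 7 to 16 in AKI_PTPi_mEVs against AKI_PBS (16 without AKI_PBS replicate 3) and 18 to 23 in AKI_PTPi_mEVs against sham with 1 library left out. With an estimated correlation camera called 0 lists in each, with 7, 3 and 7 at an unadjusted p under 0.05, and fry called 25, 20 and 11. The replicate numbers did not pair the libraries: 1 of 9 same-number pairs had a correlation of deviations over 0.1, and 2 of 9 libraries correlated best with their own number. A replicate block gave 9213, 8491 and 2050 genes and 16, 12 and 21 lists. Of 9000 values of named genes under alternatives, 8638 kept their direction and side of the threshold, 299 lost the call and 48 gained one; of 1722 for lists, 1535 kept theirs, 80 lost the call and 59 gained one. The cause was not tested.

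Direction turned in 15 gene values and 48 list values, and none of these results was called at its reported setting or at the one that turned it, though ribosomal protein in AKI_PTPi_mEVs against sham was called without AKI_PTPi_mEVs replicate 1 (0.00166). For genes the log2 fold changes, as ranges with 1 library left out or at the named setting, were Ddit3 0.072 with the GC and length correction in AKI_PBS against sham; Havcr1 -0.53 to 0.53 and -0.10 with the correction, and Ddit3 -0.055 to 0.13, -0.067 with library totals and -0.013 with the correction, in AKI_PTPi_mEVs against AKI_PBS. Against sham AKI_PTPi_mEVs had Slc5a2 -0.45 to 0.065, Ddit3 0.059 with the correction, and Insr -0.075 to 0.066, 0.00070 with no low-count filter and 0.020 with the correction. For lists, camera adjusted p in AKI_PBS against sham was 0.415 to 0.994 and 0.978 with the replicate block for endothelial cell, 0.606 to 0.996 and 0.555 with fry for red blood cell, 0.606 to 0.886 for unfolded protein response, 0.448 to 0.987 for circadian clock, and 0.752 to 0.994 and 0.979 with fry for sex-linked control. In AKI_PTPi_mEVs against AKI_PBS it was 0.635 to 0.947 and 0.836 with fry for intercalated cell, 0.427 to 0.917 for adipose tissue, 0.511 to 0.963 for nucleic acid sensor, 0.290 to 0.993 for nuclear oxidative phosphorylation, 0.649 to 0.986 for glycolysis and hypoxia, 0.539 to 0.973 and 0.836 with the replicate block for proliferation, 0.579 to 0.972 for heat shock, 0.635 to 0.899 for circadian clock, and 0.676 to 0.972 and 0.966 with library totals for sex-linked control. In AKI_PTPi_mEVs against sham it was 0.295 to 0.850 for podocyte, 0.170 to 0.927 for fibroblast and matrix, 0.295 to 0.958 for macrophage and monocyte, 0.0521 to 0.771 for urothelium, 0.496 to 0.983 for necroptosis and pyroptosis, 0.437 to 0.958 for complement, 0.00166 to 0.936 for ribosomal protein, and 0.689 to 0.994 for sex-linked control. At this depth a count of 0 in a group allows up to 3 counts, so folds of genes absent from sham are lower bounds.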

Other observations

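The tests on nuclear RNA, on the clock genes, on the proximal tubule share and on Ptpn1 were chosen after the result was seen. In AKI_PBS against sham Arntl, the core activator also called Bmal1, rose by 3.39 ± 0.21 and Npas2 by 4.44 ± 0.39, while the output regulators Dbp (-2.95 ± 0.22) and Hlf (-3.02 ± 0.16) fell. The circadian clock list, with 6 of 15 higher and 7 lower, was not called (camera adjusted p = 0.871), nor in AKI_PTPi_mEVs against AKI_PBS (5 higher, 7 lower; camera adjusted p = 0.83) or against sham (1 higher, 3 lower; camera adjusted p = 0.229). Cirbp, a cold-inducible RNA-binding protein gene, rose by 2.25 ± 0.15 in AKI_PBS and stood at -3.04 ± 0.16 in AKI_PTPi_mEVs against AKI_PBS. Its relative Rbm3 stood at 1.98 ± 0.14 and -1.59 ± 0.14. The DNA replication genes Mcm4 (1.73 ± 0.23) and Mcm7 (0.93 ± 0.23) were higher in AKI_PTPi_mEVs than sham. One gene without a symbol, ENSMUSG00000119584, took 0.404 to 0.887% of counts per library.

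The lists described next and the clock list were called by camera in no comparison at either correlation. Fry passed complement (adjusted p = 0.00407), T, B and NK cell (0.00557), necroptosis (0.0316), adrenal gland (0.0325) and fibroblast (0.049) in AKI_PBS against sham, and complement (0.00548), adrenal gland (0.0213) and T, B and NK cell (0.0231) in AKI_PTPi_mEVs against AKI_PBS. In AKI_PBS against sham macrophage and monocyte genes went both ways, 5 higher and 4 lower of 16 (camera adjusted p = 0.519), with Chil3 at 6.21 ± 0.48 and Csf1r, the receptor for macrophage growth factor, at -1.96 ± 0.16. Fibroblast and matrix genes were higher in 8 of 22 and lower in 2 (camera adjusted p = 0.281), and heat shock genes higher in 6 of 11 and lower in 3 (camera adjusted p = 0.519), with Hspb1 at 3.01 ± 0.30. Complement genes were lower in 7 of 12 and higher in 1 (camera adjusted p = 0.147), with Cfb at -1.72 ± 0.24. Podocyte genes were higher in 4 of 12 and lower in 2 (camera adjusted p = 0.518), nucleic acid sensors higher in 3 of 11 and lower in 2 (camera adjusted p = 0.518), and necroptosis and pyroptosis genes higher in 5 of 13 and lower in 2 (camera adjusted p = 0.556). Of T, B and NK cell genes 3 were measured, with 2 lower (camera adjusted p = 0.432), and of adrenal genes 1, Star (0.83 ± 0.26, camera adjusted p = 0.463). Sex-linked controls had 0 of 4 past the edgeR threshold and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.994).

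In AKI_PTPi_mEVs against AKI_PBS complement genes were higher in 8 of 12 and lower in 0 (camera adjusted p = 0.0633), with Cfb at 1.72 ± 0.24. Fibroblast and matrix genes were lower in 9 and higher in 2 (camera adjusted p = 0.167), podocyte genes lower in 6 and higher in 1 (camera adjusted p = 0.35), and macrophage and monocyte genes lower in 5 and higher in 4 (camera adjusted p = 0.305), with Chil3 at -2.49 ± 0.33. Necroptosis and pyroptosis genes were lower in 3 and higher in 1 (camera adjusted p = 0.461), nucleic acid sensors lower in 2 and higher in 1 (camera adjusted p = 0.83), heat shock genes lower in 4 and higher in 4 (camera adjusted p = 0.834), with Hspb1 at -2.39 ± 0.29, and sex-linked controls lower in 1 and higher in 1 (camera adjusted p = 0.933). T, B and NK cell genes were higher in 2 and lower in 0 (camera adjusted p = 0.385), and Star was at -1.05 ± 0.26 (camera adjusted p = 0.35).

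In AKI_PTPi_mEVs against sham nucleic acid sensors were higher in 3 and lower in 0 (camera adjusted p = 0.245), and camera adjusted p = 0.883 was shared by complement (4 higher, 2 lower), macrophage and monocyte (3 higher, 2 lower), fibroblast and matrix (2 higher, 4 lower) and sex-linked control (0 either way). Chil3 was at 3.72 ± 0.57 and Csf1r at -1.53 ± 0.16. Necroptosis and pyroptosis genes were higher in 1 and lower in 1 (camera adjusted p = 0.866). EdgeR passed 0 heat shock genes (camera adjusted p = 0.203), 0 podocyte genes and 0 T, B and NK cell genes (camera adjusted p = 0.668 for both) and not Star (-0.22 ± 0.27, camera adjusted p = 0.781), with 3, 1, 0 and 0 at an unadjusted p under 0.05, and 0 for the sex-linked controls. Counts adjusted over the list alone were the same as those given for the clock list and these lists except complement in AKI_PBS against sham (2 higher, 7 lower), macrophage and monocyte (4 higher, 6 lower) and sex-linked control (1 higher, 0 lower) in AKI_PTPi_mEVs against AKI_PBS, and nucleic acid sensor (3 higher, 2 lower), circadian clock (1 higher, 4 lower) and complement (4 higher, 3 lower) in AKI_PTPi_mEVs against sham. Median, mean and test differed in sign for endothelial cell, red blood cell, unfolded protein response and necroptosis in AKI_PBS against sham, for adipose tissue, glycolysis, proliferation and sex-linked control in AKI_PTPi_mEVs against AKI_PBS, and for macrophage, necroptosis and complement in AKI_PTPi_mEVs against sham.

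Ptpn1 was lower in AKI_PTPi_mEVs than in AKI_PBS, as were most genes raised by injury. Among 218 genes with a like rise in AKI_PBS and a like level, its change lay at percentile 41.3, and their median was -0.47. Ptpn1 fell beyond that median by 0.061 on the log2 scale (-0.061, interval -0.35 to 0.23 from 2 standard errors). The interval holds the error of Ptpn1 only and leaves out that of the median. The general return toward sham may therefore account for the lower Ptpn1, as a hypothesis. An added fall from the siRNA stays open because the interval spans both signs and reaches -0.35. No group with a control siRNA was analysed here, so the siRNA itself was not tested.

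The displacement of the clock genes could come from collection at another time of day or from injury. In AKI_PBS 11 genes moved past the threshold in the direction of an assigned arm, but those 11 were picked after the values of the 15 in the list were seen, so the count decides nothing. Members left out include Per1, which rose by 1.77 ± 0.19 where Per2 and Per3 fell, Cry2, which rose by 1.27 ± 0.22, and Nr1d1, which did not pass (0.28 ± 0.21) where Nr1d2 fell, and time of day is not given in the labels, so it cannot be told apart from the group. In AKI_PTPi_mEVs the 11 picked genes kept a median share of 0.317 of their change from sham, below the 0.605 of tubular injury genes (lower quartile 0.517). All 9488 genes changed by injury kept a median of 0.182 (quartiles -0.0765 to 0.463), so the tubular injury list was not typical of injury genes, and that comparison leaves injury open too.

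Of 14 endoplasmic reticulum chaperones, a set chosen after its values were seen, 11 were higher than sham in AKI_PTPi_mEVs. In AKI_PBS 7 were lower than sham, while Dnajb9 was higher (0.66 ± 0.23, edgeR adjusted p = 0.028). Hsp90b1 and Calr stood at 1.36 ± 0.12 and 1.40 ± 0.14 in AKI_PTPi_mEVs against AKI_PBS. The median of the proximal tubule list was -0.29 against sham (median absolute deviation 0.42) and that of the chaperones 0.71. This cannot decide whether the share of proximal tubule cells was larger. The list fell in AKI_PBS (median -1.42), so its genes may change within cells as well as with their number. The 11 calls did not depend on the scalings tried: 11 stayed called with relative log expression factors and with library totals. Library totals ended some other calls, since 2060 of the 2252 genes stayed called. These scalings moved the median of all genes by only -0.0066 and -0.028, so a larger error of normalization stays open. A response to the vesicles or their cargo may be a candidate explanation but was not tested, since no empty-vesicle group was analysed here.

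The 9488 genes changed in AKI_PBS against sham stood at 9489 after the correction for GC content and transcript length and at 9245 after thinning. Long non-coding RNA genes had a median -0.0716 from that of protein-coding genes (95% interval from resampling the former genes, -0.133 to -0.00422). That interval takes genes as independent, holds the protein-coding median fixed and leaves out the spread between libraries. Each comparison has only 10 splits of its 6 libraries, too few for a share under 0.05. The other splits also mix both groups on each side. This leaves part of the group difference in the comparison and puts part into the spread. Few changed genes could be called in such splits, and they are no reference without an effect. Counts of changed genes were 9488, 8711 and 2252 in the real splits, each reached by 1 of 10, and the highest other was 0 in each. For the return, 6905 genes moved back, reached by 1 of 10 splits of the AKI_PTPi_mEVs and AKI_PBS libraries, with 0 as the highest other. Splits of the AKI_PTPi_mEVs and sham libraries, which leave AKI_PBS whole, gave 6128 to 6216. Gene lists called were 15, 10 and 21 in the real splits, as many or more were called in 3, 8 and 1 of the 10 splits, and the highest others were 18, 18 and 14.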
